A study of Homo sapiens with 9 samples.

How the data were processed

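Long non-coding and protein-coding transcripts were measured on 9 custom Agilent oligonucleotide arrays, each hybridised with labelled cDNA from total RNA of MDA-MB-231 cells, an established human cell line from a triple-negative breast cancer. The labels put 3 arrays in each of 3 groups: control cells, cells given recombinant PAI-1, and cells given PAI-039, a small-molecule inhibitor of PAI-1. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Dose and time of treatment are not given in the sources used here. The growth protocol in the labels describes culture with leukaemia inhibitory factor on mouse embryonic fibroblasts, which is not the usual culture of this line, and the labels name Cy5 as the dye while their extract protocol names Cy3.

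Each array was scanned in 1 colour, the red channel, and its file holds 1 row per spot, per the file headers. The intensity values used were the processed signal, which is background-subtracted and spatially detrended within an array, and the median spot and local background intensities, all as deposited by the authors. Agilent Feature Extraction 10.7.3.1 is the version per the file headers, while the submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The authors' deposited table of the whole series holds linear intensity values for 54925 probes. Its median is 310.581 on every array, so the arrays were adjusted to a common median, by a method that this does not show. Its log2 values correlated across probes with those of the processed signal of the same array at 0.994 or more. How its background was treated and by which steps it was adjusted stay unknown, and it was used as an alternative.

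Each file has 56543 spots. The 31741 probes with the prefix PH_hs and the 23184 with the prefix PH_lnc were analysed, and 1439 control spots and 179 other spots were left out of the tests. The files give probe IDs without gene names, and the gene table used here does not pair these IDs with genes. What the prefixes stand for is not stated, so they are used only as probe classes. For this reason SOX2-OT, the long non-coding RNA in the series title, and SOX2, PLAU and PLAUR were not analysed here, nor were the gene lists fixed in advance, and probes were not combined into genes. The only probes that name a gene are control probes of GAPDH and PGK1, each with 10 spots per probe.

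The main values were log2 of the processed signal minus each array's 75th percentile over both probe classes. Spots flagged as outliers were set to missing. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 34287 probes (23088 PH_hs and 11199 PH_lnc). Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 1 mean per group, all 9 arrays in the fit) with Benjamini-Hochberg adjustment and a threshold of 0.05. Reading and tabulating used the R packages jsonlite 2.0.0 and data.table (version 1.17.8). The rule for named genes, fixed before the data were examined, took genes past the threshold and, where few passed, those with the smallest p. Without gene names, 1 higher and 1 lower probe with the smallest p are named for each comparison with control, and the 10 smallest p of each comparison are summarised. Where a probe was not well above background on any array of the dimmer group, its fold is a bound: the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background.

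Separation of groups was tested exactly from mean squared log2 differences between arrays over all arrangements of the arrays. The fit was tested on simulated data with the spread of the real probes. The simulated values were independent and normal, without an uneven or outlying array, so recovery on the real arrays may be lower. Of 200 probes changed 2-fold among 33940, 72% were recovered for PAI-1 minus control and 74% for PAI-039 minus control. At 4-fold the recovered shares were 98% and 97%, and at 1.5-fold 2% and 0%. These shares hold for 200 probes changing together, while a lone changed probe with the median standard error would need a 2.50-fold difference to pass the adjusted threshold in either comparison.

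Slide 1 holds 8 arrays, with all 3 groups, and PAI-039 replicate 3 lies alone on slide 2, so slide as a fixed block equals leaving out that array. On slide 1 the control arrays and PAI-1 replicate 1 lie in row 1 and the other 4 arrays in row 2. The alternatives fixed before the data were examined were quantile and median normalization, normexp background correction with an offset of 50, no filter and a filter on all 9 arrays, only the 2 groups compared, a replicate block, slide as a random block, slide 1 alone, slide row with slide as covariates, array weights, an intensity trend with a robust prior, the authors' table, fold thresholds, and leaving out each array. Normexp was run on median spot signals in place of mean spot signals, which these files do not hold. Leaving out PAI-1 replicate 1 and PAI-039 replicate 3 together, and leaving out a corner of the array surface, were chosen after the data were seen. The number of arrays limits the precision.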

Results

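Transcript levels were compared between control MDA-MB-231 cells, cells given recombinant PAI-1 (a secreted protease inhibitor) and cells given PAI-039, an inhibitor of PAI-1, with 3 arrays in each group. Between 61.3% and 64.4% of the 54925 probes were well above background on an array. The 75th percentile of processed signal lay between 2253 and 2674, and no array had more than 1 saturated probe. PAI-1 replicate 1 had 431 spots flagged as uneven, against 4 to 46 on the other arrays.

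The 3 groups did not separate. Pearson's r between arrays, across probes, averaged 0.99237 within groups and 0.992279 between groups. Mean squared log2 differences between arrays were larger between groups than within groups by 0.000661, with an exact one-sided p of 0.425 over 280 arrangements. For pairs of groups, the exact p was 0.4 for PAI-1 and control, 0.6 for PAI-039 and control and 0.7 for PAI-1 and PAI-039, where 10 splits allow no p under 0.1. The first principal component, with 25.0% of the variance, placed PAI-039 replicate 3 at 46.1 and PAI-1 replicate 1 at -31.0.

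**Figure D1:**
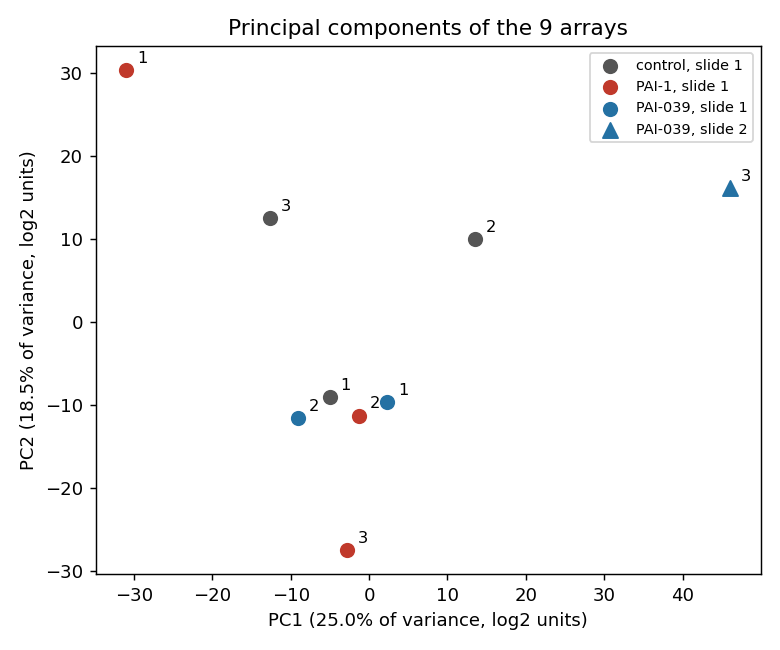
First and second principal components of the 9 arrays in log2 units, 1 point per array, coloured by group and numbered by replicate, with a triangle for the array on slide 2. PAI-039 replicate 3 lies at 46.1 on the first component, while the other arrays lie between -31.0 and 13.5.

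GAPDH, an enzyme of glycolysis, did not differ between groups by more than the spread between arrays. On the scale of log2 signal relative to the array's 75th percentile, its 3′ probe averaged 7.48 ± 0.16 (SD, n = 3) in control cells, 7.38 ± 0.17 with PAI-1 and 7.47 ± 0.12 with PAI-039. Exact permutation p-values, two-sided, were 0.5 for PAI-1 minus control and 0.9 for PAI-039 minus control. The 5′ probe averaged 7.47 ± 0.22 in control cells, 7.30 ± 0.14 with PAI-1 and 7.40 ± 0.20 with PAI-039 (SD, n = 3).

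PGK1, the enzyme that follows GAPDH in glycolysis, averaged 6.82 ± 0.08 (SD, n = 3) in control cells at its 3′ probe, 6.59 ± 0.04 with PAI-1 and 6.76 ± 0.09 with PAI-039. The difference of PAI-1 from control was -0.23, with all 3 PAI-1 arrays below all 3 control arrays, and the exact permutation p of 0.1 is the smallest that 3 against 3 arrays allow. PAI-1 minus PAI-039 was -0.17 at this probe, also with an exact p of 0.1. The PGK1 5′ probe gave 4.60 ± 0.43 in control cells and 4.54 ± 0.15 with PAI-1 (SD, n = 3), a difference of -0.06 with an exact p of 0.9. The difference between the 3′ and 5′ probes changed by -0.17 from control to PAI-1, with an exact p of 0.5. These control probes were examined without a multiple-testing correction.

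**Figure D2:**
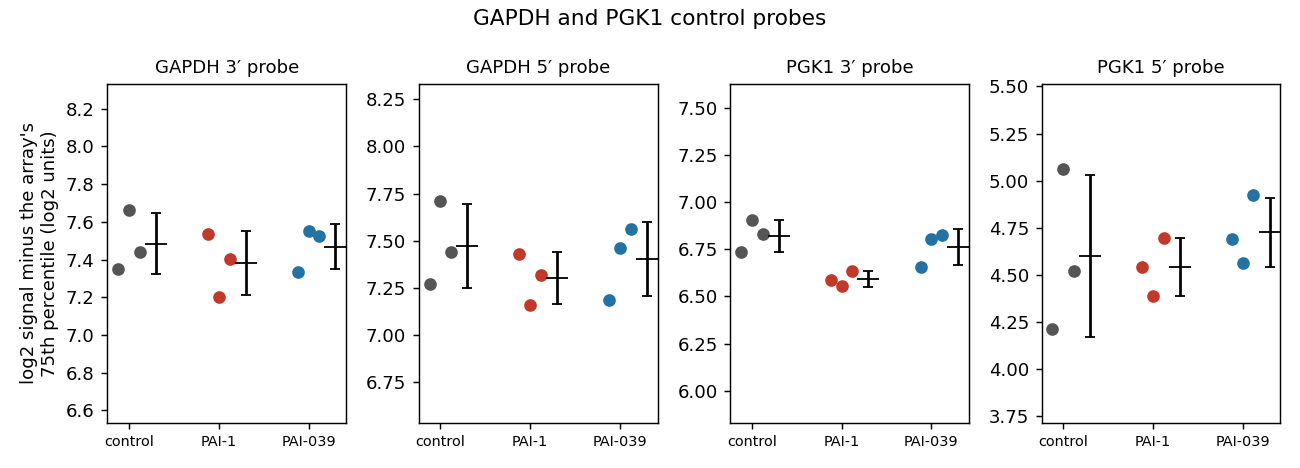
Log2 signal of the GAPDH and PGK1 control probes minus each array's 75th percentile, with 1 point per array and a black mark with bars for the mean and SD of the 3 arrays of a group. At the PGK1 3′ probe the PAI-1 arrays averaged 6.59 and the control arrays 6.82.

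The comparison of PAI-1 with control cells asks which transcripts change when the protein is added. No probe of 34287 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.348. At an unadjusted p under 0.05 there were 1121 probes (473 higher and 648 lower), or 3.27%, where 1714 would come from 5% of the probes, and without PAI-1 replicate 1 the count was 1857. The balance of directions turned under normexp, with 963 of 1227 higher. Over the probes, the median standard error of a difference was 0.15, and the median 95% interval reached 0.32 on either side, in log2 units. For 97.3% of the probes the interval lay within 2-fold. PH_lnc_0010913 had the smallest p. Its log2 signal relative to the 75th percentile averaged -2.92 ± 1.05 (SD, n = 3) with PAI-1 and -5.92 ± 0.28 in control cells, where it was not well above background, so it was at least 2.76-fold higher with PAI-1 (limma adjusted p = 0.348). Without PAI-1 replicate 1, which lay highest at -1.72, the bound was 1.81-fold. Its mean with PAI-039 was -6.23 ± 0.40 (SD, n = 3). PH_lnc_0013959 was the leading lower probe, with a log2 difference of -0.59 ± 0.12 (SE) and a limma adjusted p of 1.00, and it was well above background on 1 of the 3 PAI-1 arrays. Of the 10 probes with the smallest p, 6 were higher and 4 lower with PAI-1.

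Probes with a difference of at least 2-fold at an unadjusted p under 0.05 numbered 28, of which 27 were higher with PAI-1, and 17 to 198 when an array was left out, the most without PAI-1 replicate 3. All 28 lay in rows 2 to 39 and columns 9 to 71 of an array surface of 384 rows and 164 columns, a rectangle drawn around them that holds 3.81% of the tested probes. PAI-1 replicate 1 was brighter than the other arrays in 9 of 288 surface blocks, found on probes left out of the tests. These blocks held 3.13% of the tested probes and 19 of the 28, and PH_lnc_0010913 lay in them at row 7 and column 11. Leaving out PAI-1 replicate 1 gave 2 probes past the threshold (both in these blocks), leaving out PAI-1 replicate 2 gave 29 (25 of them in these blocks) and leaving out PAI-1 replicate 3 gave 47 (26 in these blocks), while leaving out any control or PAI-039 array gave 0.

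**Figure D3:**
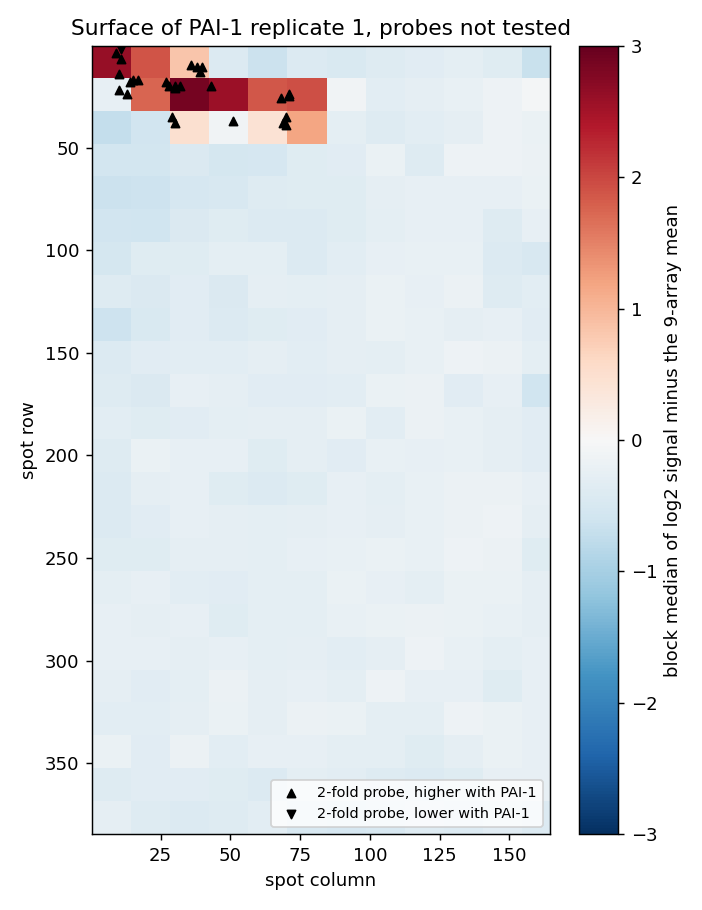
Surface of PAI-1 replicate 1, with spot columns and spot rows as axes and, in colour, the median per block of log2 signal minus the mean of the 9 arrays over probes left out of the tests. Triangles mark the 28 probes that differed at least 2-fold between PAI-1 and control at an unadjusted p under 0.05, all of them in rows 2 to 39.

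The comparison of PAI-039 with control cells asks which transcripts change when PAI-1 is inhibited. No probe of 34287 passed an adjusted p of 0.05 in limma, with a smallest adjusted p of 0.344. At an unadjusted p under 0.05 there were 2236 probes (1052 higher and 1184 lower), or 6.52%, and without PAI-039 replicate 2 there were 3433. Neither direction held across settings, since 1720 of 2898 were higher under normexp and 875 of 3006 in the authors' table. They made up 7.81% of the PH_hs probes and 3.86% of the PH_lnc probes, a difference between the classes that was not tested. PH_hs_0035403 was the leading higher probe, at -1.11 ± 0.25 (SD, n = 3) with PAI-039 and -2.04 ± 0.03 in control cells, a log2 difference of 0.93 ± 0.13 (SE) with a limma adjusted p of 0.344. PH_hs_0027789 was the leading lower probe, at 2.82 ± 0.09 (SD, n = 3) with PAI-039 and 3.63 ± 0.18 in control cells, a log2 difference of -0.81 ± 0.12 (SE) with the same adjusted p. Both were well above background on all 9 arrays, and their PAI-1 means lay between the other groups, at -1.57 ± 0.06 and 3.22 ± 0.07 (SD, n = 3). The 10 probes with the smallest p differed from control by 0.69 to 0.95 in log2 units, 7 of them higher. For 97.7% of the probes the 95% interval lay within 2-fold, and 13 probes differed at least 2-fold at an unadjusted p under 0.05, or 13 to 51 when an array was left out, the most without PAI-039 replicate 3. Within slide 1, that is without PAI-039 replicate 3, 2 probes passed the threshold.

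The comparison of PAI-1 with PAI-039 sets added protein against its inhibitor. No probe of 34287 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.131. There were 1455 probes at an unadjusted p under 0.05 (604 higher and 851 lower with PAI-1), and 16 of them differed at least 2-fold. Without PAI-039 replicate 2 there were 3368, of which 2005 were higher with PAI-1, and the balance of directions also turned under normexp (844 of 1571 higher) and array weights (1945 of 3585 higher), among other settings. The number at 2-fold ran from 13 to 196 when an array was left out, the most without PAI-1 replicate 3. The 95% interval lay within 2-fold for 97.4% of the probes. Within slide 1, 2 probes passed the threshold, and leaving out PAI-1 replicates 1, 2 or 3 in turn gave 2, 29 and 43, of which 2, 25 and 24 lay in the raised blocks of PAI-1 replicate 1.

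**Figure D4:**
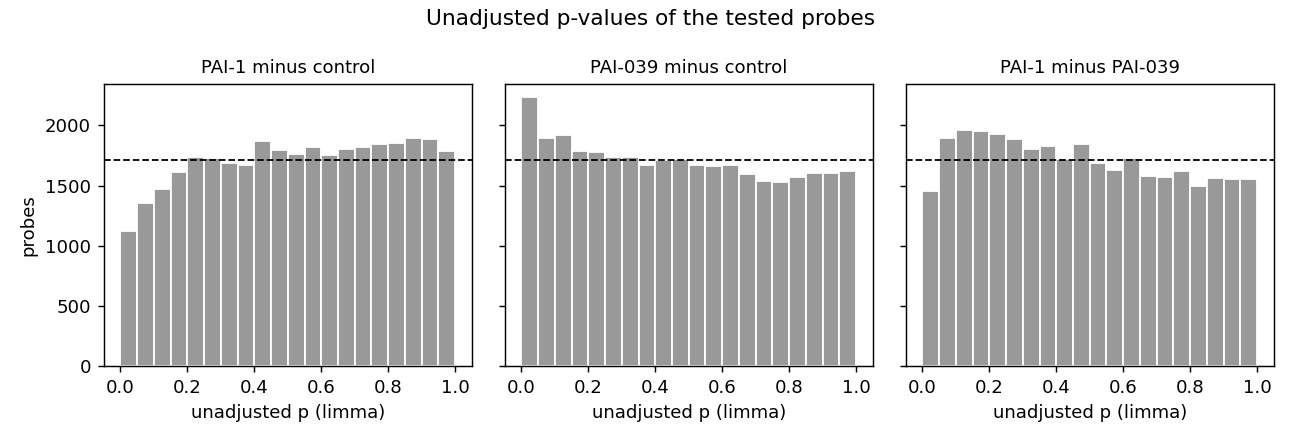
Unadjusted limma p-values of the tested probes in bins of 0.05 for the 3 comparisons, with the number of probes on the vertical axis and a dashed line at the number per bin if p-values were uniform. The lowest bin holds 1121 probes for PAI-1 minus control, 2236 for PAI-039 minus control and 1455 for PAI-1 minus PAI-039.

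Differences of both treatments from the shared controls correlated across 33940 probes with r = 0.44 (Spearman's rho 0.40), and probes are not independent replicates. Unchanged groups simulated against shared controls gave an r of 0.50. The covariance was 0.0149 against a simulated 0.0174, a difference of -0.00251. Over all 840 ways of naming the arrays, r ranged from 0.170 to 0.770, and 263 of them gave an r at or below the observed. At an unadjusted p under 0.05, 261 probes were higher in both comparisons and 123 lower in both, where simulation gave 212.6 and 215.1 and independent lists would give 14.5 and 22.4. The real lists held 473 and 1052 higher and 648 and 1184 lower probes for PAI-1 and PAI-039. Simulated lists were not matched to these sizes, so an excess or deficit against simulation may partly reflect list size. Opposite calls numbered 0, where the same simulation gave 7.18. The 3 control arrays cannot be divided so that each part keeps 2. Shared controls without any change gave 212.6 and 215.1 shared probes in simulation. The excess over independent lists is therefore no evidence of a shared response.

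**Figure D5:**
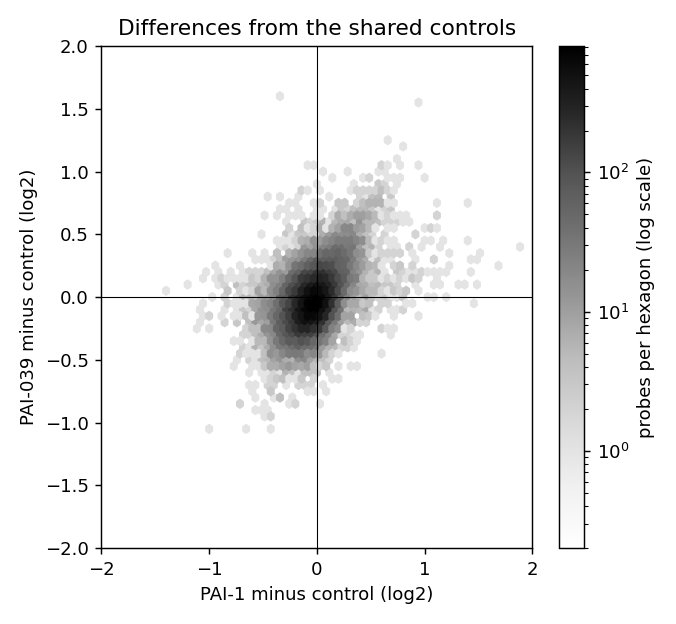
Log2 difference of PAI-039 from control against that of PAI-1 from control for the tested probes, shaded by the number of probes per hexagon on a log scale. The correlation across probes is 0.44, against 0.50 simulated for unchanged groups, and 2 probes lie outside the axes.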

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

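Leaving out PAI-1 replicate 1 and PAI-039 replicate 3 together, leaving out the raised blocks of the array surface, and the alternatives for group separation and for the detection flag were chosen after the data were seen. No probe passed the threshold in any of the 3 comparisons under quantile or median normalization, normexp, no filter, a filter on all 9 arrays, a random slide block, the trend with robust prior, the authors' table, or without the raised blocks of the surface. With the replicate block no probe passed either, and unadjusted counts were 923, 1754 and 1178. Replicate numbers did not pair the arrays: 1 of 9 same-numbered pairs had correlated deviations over 0.1, and 2 of 9 arrays correlated best with their own number. Slide row with slide as covariates gave 568 probes for PAI-1 minus control, 349 for PAI-039 minus control and 2 for PAI-1 minus PAI-039. By its construction that fit rests both comparisons with control on PAI-1 replicate 1, the only treated array in the controls' row of slide 1, and 244 of the 568 lay in the raised blocks. Array weights gave 1 probe for PAI-1 minus PAI-039, the fit of only the 2 groups gave 1 for PAI-039 minus control, and the cause was not tested. Slide 1 alone gave 2 probes for PAI-039 minus control and 2 for PAI-1 minus PAI-039. Without PAI-1 replicate 1 and PAI-039 replicate 3 together, 2, 4 and 8 probes passed. An unadjusted p under 0.05 with a 2-fold difference gave 28, 13 and 16 probes, and 17 to 198, 13 to 51 and 13 to 196 when an array was left out. These 2-fold counts were 136, 56 and 176 with no filter, 17, 5 and 4 under normexp, 514, 633 and 45 with slide row and slide, and 31, 57 and 76 with array weights. Counts at an unadjusted p under 0.05 alone ranged over all settings run from 852 to 2905 (no filter, 439 higher; array weights 2437), 1754 to 4146 (array weights, 1514 higher) and 1076 to 3585 (array weights). For PAI-039 minus control, quantile normalization gave 1269 of 2307 higher. Leaving out each array in turn, 0 to 47 probes passed for PAI-1 minus control, 0 to 2 for PAI-039 minus control (2 without PAI-039 replicate 3) and 0 to 43 for PAI-1 minus PAI-039. The correlation of both treatments' differences ranged from 0.303 to 0.582 when an array was left out, lowest without PAI-039 replicate 2 and highest without control replicate 1. Separation of the groups stayed above a p of 0.1 in all settings run, the lowest being 0.107 without PAI-039 replicate 2. Mean or separate treatment of a gene's probes, SOX2-OT and the gene lists were not run, since probes carry no gene names here. Signal over background limits the rest: 37.6% of the probes were left out of the tests.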

Other observations

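Tests on dim spots, on where probes lay on the surface, on the slide, on RNA integrity and on PGK1 cross-hybridisation were chosen after the patterns were seen. The fits without each array were planned, but setting those without PAI-1 replicates 2 and 3 against the count without PAI-1 replicate 1 was decided after their counts were seen. Bounds for the surface test over all probes, for the count without PAI-1 replicate 1, for quantile normalization, for mouse RNA and for splits were written beforehand.

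Probes well above background on all 3 arrays of one group and on none of the other numbered 24 with PAI-1 alone and 47 with control alone in that comparison, a total of 71, where other splits of the 6 arrays gave 43 to 82. For PAI-039 and control the numbers were 10 and 39, a total of 49 against 19 to 89 in other splits. For PAI-1 and PAI-039 they were 31 and 8, a total of 39 against 36 to 142. With the flag for positive and significant signal, 4 probes were seen with PAI-1 alone and 421 with control alone, a total of 425 against 23 to 174 in other splits. Only the real split reached that total, but 10 splits allow no share under 0.1, so the total does not establish an effect of PAI-1. Under that flag the numbers were 10 and 65 for PAI-039 and control, a total of 75 against 30 to 315. For PAI-1 and PAI-039 they were 0 and 49, a total of 49 against 30 to 450. The direction of this last comparison was thus opposite to that under the first flag, which gave 31 and 8.

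Other splits of the arrays were counted for each comparison. Past the adjusted threshold the real count was 0, so 10 of 10 splits necessarily gave as many, which decides nothing, and the highest other count was 0. At an unadjusted p under 0.05, PAI-1 minus control had 1121 probes, 4 of 10 splits had as many, and the highest other had 3287. PAI-039 minus control had 2236, 5 of 10 splits had as many, and the highest other had 3515. PAI-1 minus PAI-039 had 1455, 6 of 10 splits had as many, and the highest other had 3255. With 10 splits no share under 0.05 can be reached.

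PAI-1 replicate 1 was uneven across its surface, and most of the 2-fold differences of PAI-1 from control lay there. The test set in advance, the SD of block medians over all probes, did not single the array out. Its ratio to the highest other array was 0.949, short of the bound of 1.5. A patch of 9 among 288 blocks adds little to that SD, so the test does not exclude a shift of brighter probes there. The only 2-fold probe lower with PAI-1, PH_hs_0033073, lay in the patch at row 2 and column 11. Its log2 difference was -1.07, with an SD of 1.16 on the PAI-1 arrays and 0.54 on the control arrays. Added signal does not account for a lower value, and whether the unevenness lowered brighter probes was not tested. Over dim probes left out of the tests, a choice made afterwards, the ratio was 2.68. Of the 28 2-fold probes, 19 lay in the 9 raised blocks (Fisher's exact test, one-sided p = 1.2e-22). A candidate explanation for most of these differences is added signal on dim spots, with 9 probes at 2-fold once those blocks are left out. The 9 of the 28 outside the raised blocks also lay in rows 2 to 39, in blocks bordering the raised ones. Dim-probe medians of these bordering blocks ran from -0.237 to 0.478, against a limit of 0.5 for a raised block. These 9 therefore cannot be set apart from the patch. Leaving out the array gave 2 probes past the threshold, a rise by the bound set in advance, but leaving out PAI-1 replicate 2 or 3 gave 29 and 47, and leaving out any control or PAI-039 array gave 0. Both probes, and 25 and 26 of the others, lay in the raised blocks, so whether the uneven surface hid effects of PAI-1 cannot be told apart from local signal there. PH_lnc_0010913 lies in the same blocks. Without the array its bound was 1.81-fold, and its log2 difference of 2.39 had a limma adjusted p of 0.00831 (1.3e-05 to 1.00 across alternatives). Dim spots over 2-fold above the other groups were 5.55 and 4.76 times as frequent there as elsewhere on PAI-1 replicates 2 and 3. The ratios were 4.70 and 3.16 on PAI-039 replicates 1 and 2, but 0.668 to 1.67 on the controls and 0.959 on PAI-039 replicate 3. These PAI-1 and PAI-039 replicates with higher ratios lie in row 2 of slide 1 and all controls in row 1, so slide row and treatment cannot be told apart. The PAI-039 ratios rest on 145 dim spots and a reference that includes PAI-1 replicate 1, the PAI-1 ratios on 571. The control ratios have the same limit of reference and rest on 3, 1 and 1 raised spots among 129 to 130. On PAI-039 replicates 1, 2 and 3 the raised spots numbered 15, 7 and 4, so the contrast with the controls hangs on few spots. Local signal may account for PH_lnc_0010913 too, and an effect of PAI-1 on it stays open.

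PAI-039 replicate 3 stood apart, with a mean squared log2 difference to the other arrays of 0.142 against 0.0862 to 0.129 for the others. Quantile normalization left it highest, at 0.143 against at most 0.124, which argues against scale or intensity trends as the whole cause. Its PGK1 3′ minus 5′ difference of 1.90 lay within the 1.84 to 2.52 of the other arrays, which argues against more degraded RNA. Its mean difference to the other PAI-039 arrays, 0.135, lay inside the range of same-group pairs on slide 1, 0.0705 to 0.140, but above 0.102, the highest when PAI-1 replicate 1 is left out. It is the only array on slide 2, so slide, culture and array cannot be told apart, and an effect of PAI-039 in that culture alone was not tested.

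Control probes for mouse PGK1 and GAPDH were well above background on all 9 arrays, and the labels' growth protocol names mouse feeder cells, but so were rat GAPDH 3′, GAPDH 5′ and PGK1 5′ probes, though no rat cells are named. Among other mouse-prefixed probes 6 of 9 were above background, and among rat-prefixed probes 12 of 22 (Fisher's exact test, one-sided p = 0.417), which decides neither for nor against mouse RNA. The mouse PGK1 5′ probe followed the human PGK1 5′ probe over the 9 arrays, with r = 0.978 (exact permutation p = 5.5e-06) and rho = 0.983 (exact permutation p = 5.0e-05), and r = 0.960 without the 2 arrays farthest from the median. Against human GAPDH 5′ and PGK1 3′ its r was 0.616 (exact permutation p = 0.0766) and 0.446 (exact permutation p = 0.229). Other probes were not compared in this way. On control replicates 1 and 2 the mouse PGK1 5′ probe lay at 2.10 and 3.03, its lowest and highest values. The rat GAPDH 5′ probe, of another gene, moved likewise there, at 5.65 and 6.45. A link specific to PGK1 is therefore not established. Cross-hybridisation of human PGK1 RNA is a candidate explanation for that probe, and no biological explanation was tested.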
